A study of Mus musculus with 5 samples.

How the data were processed

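RNA from sorted CD4 T cells of the colon was hybridised to 5 Affymetrix arrays, 3 from conditional and 2 from control mice, with groups taken from the genotype labels and replicate numbers from the titles. Total RNA was extracted, amplified to cDNA with a whole-transcript kit and biotin-labelled, per the labels' protocols, which give an RNA integrity number of at least 9.2 for every sample. The deposited values are log2 signals of one table, made with RMA in the oligo package per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays together and summarises probes, so a global shift in RNA content is removed and differences of dim genes are compressed. The versions of these tools and the genome build are not given in the sources used here, and no coordinates are printed. Positions in a reference gene table served only to order genes for the test of neighbouring genes. Array medians over all probe sets lay between 7.12 and 7.23. Arrays carry no read depth, and their number limits the precision.

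The table held 34760 probe sets. The platform's gene annotation, which is from an older release, gave 1 gene symbol for 21640, several for 1321 and was silent on 11799, which are unnamed here. Of the symbols, 21553 were found by gene number in a reference gene table (assembly GRCm38.p6) and 0 needed updating. Each of 19937 genes was represented by its probe set with the highest mean over all arrays, and 954 genes had several. No 2 arrays held identical values.

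Conditional and control arrays were compared with limma (version 3.58.1 in R 4.3.3), lmFit and eBayes with default settings and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Residual degrees of freedom were 3, and the prior added 2.10. Before the data were examined, 30 gene lists were fixed, with 569 genes of which 508 were measured. They were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. Of these, 16 passed, 12 higher and 4 lower, 0 passed with an estimated correlation and 2 passed with fry, the effector-memory and the granulocyte and mast cell lists. Counts adjusted over the list alone used the same p-values adjusted within each list.

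The genes named were chosen by a rule fixed at the same time. It takes calcineurin subunit genes and 15 genes of T cell identity, the 12 largest changes in each direction among genes past the threshold with groups fully apart (filled by the smallest p where fewer qualified), and for each list up to 6 members past the threshold or otherwise up to 4 with the smallest p. Predicted genes, small RNAs and receptor variable segments were counted and not named by this rule, which left 4 genes past the threshold unnamed by it. Of 20 genes always named, 17 were analysed here and 3 were not analysed here.

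The procedure was tested on simulated arrays with the real genes' mean levels and variances drawn from the fitted prior. Simulated genes were independent and varied alike on every array, whereas control replicate 1 stood apart in the real data. The simulated shares, including that of false calls, therefore need not hold for the real calls. In 20 runs with 200 of 19937 genes changed, the conditional against control test recovered 19.3% of genes changed by 1 on the log2 scale, 78.4% at 2 and 94.5% at 4, and 5.02% of calls were false. Camera recovered 20 of 20 planted lists and called 1 of 580 unchanged lists, with genes simulated as independent. Alternatives were another normalization, filters on dim genes, other choices of probe set, a variance trend, array weights, the replicate number as a block, each array left out in turn, other thresholds and other list tests. The mean of the T cell receptor list as a covariate was added after control replicate 1 was seen to stand apart, for genes, lists and, with limma, list means per array.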

Results

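Gene expression was measured in CD4 T cells with low surface CD44, sorted from the lamina propria of the mouse colon, the connective tissue layer beneath the gut epithelium. The comparison was between mice carrying a floxed gene for the regulatory subunit of calcineurin (Cnb1, gene symbol Ppp3r1) together with a Cre recombinase driven by CD4, called conditional here, and mice with the floxed gene and no Cre, called control. Calcineurin is the calcium-dependent phosphatase that activates NFAT transcription factors after T cell receptor engagement. There were 3 conditional arrays and 2 control arrays, and the number of arrays limits the precision of every value. The series describes 3 independent experiments with 3 to 5 mice per group, while the files hold 2 control arrays. The labels say neither whether an array held RNA pooled from several mice nor whether equal replicate numbers mark the same experiment. The p-values therefore measure the spread between these samples, which may be technical. On pooling, every array read both Xist, a transcript of female cells (10.34 to 11.74), and the Y-linked gene Eif2s3y (8.21 to 9.33). RNA from mice of both sexes on each array would give this, but no call against background was available. The question named by the study was whether calcineurin B restrains genes of Th1 differentiation and of JAK/STAT signalling in these cells.

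The targeted gene, Ppp3r1, was read at a log2 level of 8.64, 8.83 and 8.77 in conditional replicates 1, 2 and 3, and of 8.99 and 8.60 in control replicates 1 and 2. The difference was -0.05 ± 0.159 (SE, limma, adjusted p = 0.927), with a 95% confidence interval from -0.46 to 0.35. The sources used here do not name the deleted exons, and the probe set may lie outside them, in which case its level checks nothing about the deletion. The other calcineurin subunit genes did not pass the test either, at -0.21 for Ppp3ca, 0.16 for Ppp3cb, -0.08 for Ppp3cc and 0.10 for Ppp3r2. Directions turned with the control array, to 0.15 for Ppp3r1 and 0.23 for Ppp3ca without control replicate 1 and to 0.48 for Ppp3cc without control replicate 2, and Ppp3r2 was at 0.04 without conditional replicate 3.

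The genes most raised in conditional cells included Il12rb2, the signalling chain of the interleukin-12 receptor, which stood at 11.61 ± 0.151 (SD, n = 3) against 7.67 ± 0.0816 (SD, n = 2) in control cells, 15.4-fold higher (limma, adjusted p = 0.0112). Kcnma1, a calcium-activated potassium channel, was 58.8-fold higher, Klrc1, the NKG2A inhibitory receptor of natural killer and T cells, 48.1-fold, and Il1a, an inflammatory cytokine, 38.5-fold, each at an adjusted p of 0.0112. Clec4e, a pattern recognition receptor best known from myeloid cells, rose 25.8-fold, and Acod1, the mitochondrial enzyme that makes itaconate, rose 11.5-fold. The cystine transporter gene Slc7a11 rose by 3.45 on the log2 scale, and the prohormone convertase gene Pcsk1 (11.4-fold), Ermn (11.7-fold), Klrc2 (10.4-fold), Igsf6 (9.53-fold) and Ttc39c (8.51-fold) were the others of the 12 largest increases. The other probe set of Kcnma1 went the opposite way, at -0.78, and Klrc1 and Klrc2 are paralogs whose probe sets may share signal. In control cells Klrc1, Il1a, Klrc2, Clec4e, Igsf6, Ermn and Kcnma1 lay at the 8.64, 13.3, 14.5, 17, 20.2, 22.3 and 23.7 percentiles of all genes, with no call against background, so their folds are approximate and their order is not firm.

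The genes that fell numbered 9, against 74 that rose. Hspb1, a small heat shock protein gene, fell by 2.50 on the log2 scale, from 11.54 to 9.04 (limma, adjusted p = 0.0496). Tet1, which encodes a DNA demethylation enzyme, fell by 1.76, Dzip1 fell by 1.78, and Fos, an immediate-early transcription factor gene, fell by 1.56. Krt20 and Cdhr5, genes of the gut epithelium, fell by 1.67 and fell by 1.41. Mboat1, Pxylp1 and Rasl11b were the remaining genes that fell, at -1.53, -1.15 and -1.04. Next in order, Slc25a23, Myo15b and Prss23 were at -1.14, -2.13 and -1.67 and did not pass the threshold, with adjusted p of 0.0505, 0.0505 and 0.0545.

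Of 19937 genes, 83 passed an adjusted p of 0.05 in limma, 74 higher and 9 lower in conditional cells, and in all 83 the 3 conditional values lay on one side of both control values. Among all genes 6073, or 30.5%, had groups fully apart in this way, where chance gives 20%. Leaving out any 1 conditional array gave 0 genes past the threshold (limma, with between 1417 and 2037 genes at an unadjusted p of 0.05). All 83 genes kept their direction in each of those fits, which was bound to happen, since their groups were fully apart. They also kept an unadjusted p under 0.05 in limma, but they had been chosen by their p in the same data. Leaving out control replicate 1 gave 1217 genes (665 higher, 552 lower) and leaving out control replicate 2 gave 5474 (2190 higher, 3284 lower), so the balance of directions is not firm. Array weights gave 13 genes.

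**Figure D1:**
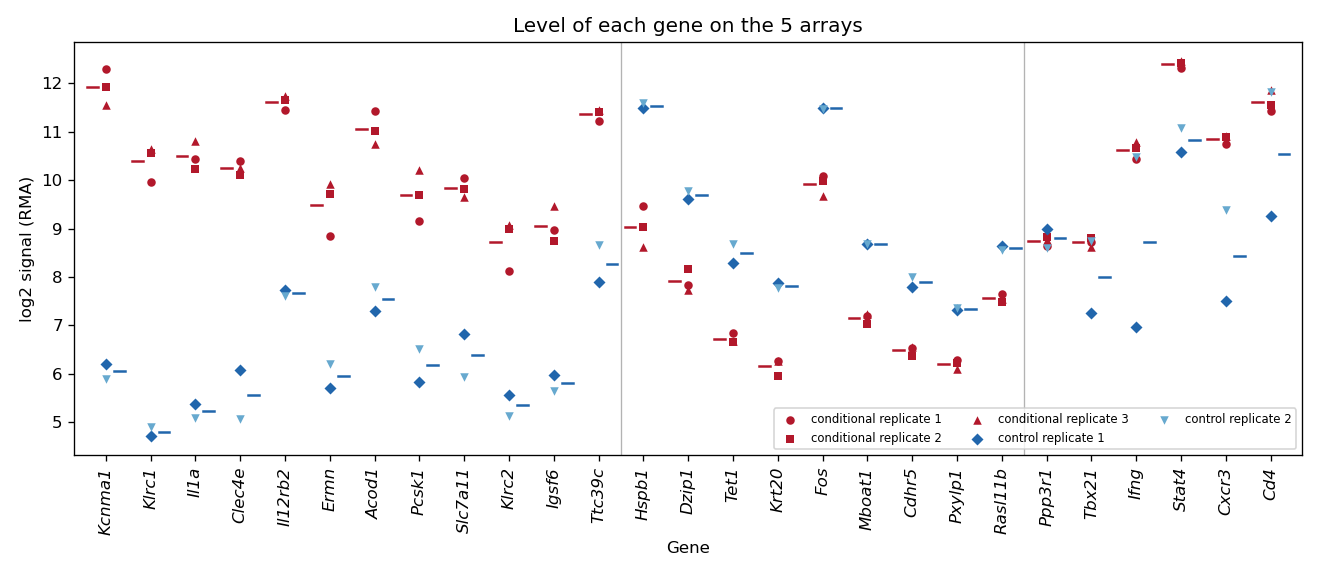
Log2 RMA signal of single genes on each of the 5 arrays, with symbols for arrays and short bars for the mean of each group; the first block holds the 12 largest increases, the second the 9 genes that fell, and the third Ppp3r1 and 5 genes of T cell identity or Th1 function. For Il12rb2 the conditional mean was 11.61 and the control mean 7.67, whereas Ifng in control replicate 2 (10.48) lay among the conditional arrays.

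Genes of the Th1 programme were higher as a group in conditional cells. Il12rb2 rose, and 1 of the 27 measured members passed the test over all genes. Adjusted over the list alone, 9 were higher and 1 was lower. Cxcr6, a chemokine receptor of tissue T cells, differed by 3.09 (adjusted p = 0.0501), Stat4, the transducer of interleukin-12 signals, by 1.56 (adjusted p = 0.0545) and Havcr2, the TIM-3 receptor gene, by 1.76 (adjusted p = 0.0617), none of them past the threshold. Tbx21, which encodes the Th1 master regulator T-bet, differed by 0.71 (adjusted p = 0.537), Ifng by 1.91 (adjusted p = 0.469) and Cxcr3 by 2.42 (adjusted p = 0.157). The list median was 0.86 (camera, adjusted p = 4.04e-06; adjusted p = 0.733 with an estimated correlation). Against control replicate 1 alone the list median was 1.78, against control replicate 2 alone it was 0.15, Ifng differed by 0.15, Cxcr3 by 1.48 and Tbx21 by -0.04, and without control replicate 1 the list no longer passed (adjusted p = 0.176).

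JAK/STAT components and cytokine receptors were also higher as a group, with a median of 0.42 over 27 genes (camera, adjusted p = 0.000111; adjusted p = 0.733 with an estimated correlation). Il12rb2 was the 1 member that rose over all genes, and 11 were higher and 3 lower adjusted over the list alone. Several members, Il12rb2, Stat4 and Ifngr1 among them, also belong to the Th1 programme above, so these results are not separate. Other T cell lists share genes as well. Ifngr1, a chain of the interferon-gamma receptor, differed by 0.71 (adjusted p = 0.0809), and Il6ra, the interleukin-6 receptor gene, by -1.72 (adjusted p = 0.0672). The list median was 0.20 without control replicate 1 and 0.76 without control replicate 2, and the list passed in both cases (adjusted p = 0.0112 and 5.77e-06). The negative regulators of the pathway had a median of 0.13 over 18 genes and did not pass (camera, adjusted p = 0.542), with none past the test and 0 adjusted over the list alone. Socs1 differed by 0.10 (-0.48 without control replicate 1), Socs3 by -0.26 and Socs7 by 0.54.

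Interferon-gamma response and antigen presentation genes were higher, with a median of 0.45 over 22 genes (camera, adjusted p = 0.000147; adjusted p = 0.698 with an estimated correlation). Cxcl9, a chemokine induced by interferon-gamma, rose by 1.58, and Gbp3, a guanylate-binding protein gene, rose by 1.16. Adjusted over the list alone 4 were higher. The list median was 0.14 against control replicate 2 alone and 0.70 against control replicate 1 alone, and the list did not pass without control replicate 1 (adjusted p = 0.0853). Interferon-stimulated genes did not pass, with a median of 0.08 and a test in the opposite direction (camera, adjusted p = 0.881). None of the 29 passed over all genes and 0 adjusted over the list alone; Ifit1 was at 0.65 and Ifit3 at -0.69 (-0.44 without control replicate 1).

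Against the mean of both controls, genes of regulatory T cells had the largest median of the T cell lists, 1.22 over 20 genes (camera, adjusted p = 1.19e-05, and 0.733 with an estimated correlation). By list mean, the regulatory list (0.98) came after the Th1 (1.13) and T cell receptor (1.01) lists. Tnfrsf9, the costimulatory receptor 4-1BB, rose 4.11-fold, and adjusted over the list alone 8 members were higher. Foxp3, the lineage regulator, differed by 1.47 (adjusted p = 0.328), Tgfb1 by 1.04 and Ebi3 by 1.75. Without control replicate 1 the median was 0.73 (adjusted p = 6.65e-06) and Foxp3 was at 0.54, and without control replicate 2 they were at 2.06 and 2.41. Effector-memory genes had a median of 0.67 over 26 genes (camera, adjusted p = 0.000381; adjusted p = 0.350 with an estimated correlation), Rora rose 2.04-fold, and 7 were higher adjusted over the list alone. Without control replicate 1 the effector-memory median was 0.39. Cd44, the receptor used in the sort, differed by 0.81 (adjusted p = 0.115), and Gzma by 1.004.

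Gut homing genes had a median of 0.92 over 18 genes (camera, adjusted p = 0.00624; adjusted p = 0.740 with an estimated correlation), with none past the test over all genes and 0 adjusted over the list alone. Itgae differed by 2.61 and Gpr15 by 1.82 (1.39 and 1.02 without control replicate 1), and the list median was 1.77 without control replicate 2. The gut homing list did not pass without control replicate 1 (median 0.20, adjusted p = 0.440) or without conditional replicate 2 (adjusted p = 0.0580). T cell receptor genes had a median of 1.003 over 20 genes (camera, adjusted p = 0.00894; adjusted p = 0.781 with an estimated correlation), with none past the test and 0 adjusted over the list alone. Cd4 differed by 1.07 (adjusted p = 0.580) and Trat1 by 2.76, but against control replicate 2 alone Cd4 was at -0.21 and Trat1 at 0.76. The T cell receptor median was 2.32 against control replicate 1 and -0.37 against control replicate 2, so without control replicate 1 it turned and passed as lower (adjusted p = 0.00115), and it did not pass without conditional replicate 2 (adjusted p = 0.0667). Proliferation genes (median 0.26 over 29 genes; camera, adjusted p = 0.0216; adjusted p = 0.781 with an estimated correlation) and glycolysis genes (median 0.31 over 17 genes; camera, adjusted p = 0.0244; adjusted p = 0.733 with an estimated correlation) passed with 0 and 1 members higher adjusted over the list alone. Top2a differed by 1.15 (0.58 without control replicate 1), with its other probe set at -0.22, and Slc16a3 by 0.81. Neither list passed without control replicate 1 (medians 0.06 and 0.13, adjusted p = 0.645 and 0.292), proliferation did not pass without conditional replicate 3 (median 0.07, adjusted p = 0.376) and had a median of 0.40 without control replicate 2, and glycolysis did not pass without conditional replicate 2 (adjusted p = 0.107). Neither passed with the median filter (adjusted p = 0.334 and 0.118) or the replicate block (adjusted p = 0.211 and 0.0561).

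The calcineurin-NFAT pathway genes did not shift as a group, with a median of -0.004, a mean of 0.0007 and a camera adjusted p of 0.939 over 30 genes, and none passed over all genes or adjusted over the list alone. Nfatc3 differed by 0.72 and Orai1 by 0.85 (0.35 and 0.25 without control replicate 1). T cell activation and NFAT target genes did not pass as a list (median 0.11; camera, adjusted p = 0.452), although Tnfrsf9 rose and Cblb, a ubiquitin ligase gene that dampens T cell activation, rose by 0.96. Adjusted over the list alone, 3 of these 32 genes were higher and 2 lower, and Egr2 was at -1.22 (adjusted p = 0.0546) and Csf2 at 0.96.

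Th2 genes (median 0.26 over 13 genes; camera, adjusted p = 0.0662), Th17 genes (median 0.19 over 16 genes; adjusted p = 0.239) and follicular helper genes (median -0.04, mean 0.14, adjusted p = 0.674) did not pass as lists, and neither did naive T cell genes (median -0.01; adjusted p = 0.553) or apoptosis and survival genes (median 0.16; adjusted p = 0.187). Rora, a Th17 regulator, rose, and Gata3 and Il17a differed by 1.55 and 0.19 (0.23 and -0.19 without control replicate 1). Adjusted over the list alone, 0 Th2 genes passed, 4 Th17 genes were higher and 2 lower, 1 follicular helper gene was higher and 2 lower, 2 naive genes were lower, and 3 survival genes were higher, with Bcl2l1 at 0.92. Some list calls turned on 1 control array or on the processing. The Th2 list passed after another quantile normalization, median centring, array weights and the replicate block (adjusted p = 0.0255, 0.0255, 0.0322 and 0.0462), and the T cell activation and survival lists passed with that block (adjusted p = 0.0228 and 0.0449). Leaving out conditional replicate 3 gave the same medians as the block. There the Th2, T cell activation and survival lists did not pass (camera, adjusted p = 0.0824, 0.191 and 0.101). Without control replicate 1 the Th2 and T cell activation medians turned to -0.10 and -0.22 and the survival median was -0.003, and without control replicate 2 the Th2 and Th17 medians were 0.56 and 0.44. Without control replicate 2, the Th2, survival, naive and T cell activation lists passed as higher (adjusted p = 0.000233, 0.00926, 0.00339 and 0.000233). Without control replicate 1, the naive, follicular helper and interferon-stimulated lists passed as lower (adjusted p = 6.65e-06, 0.0426 and 0.0267).

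Stress and immediate-early genes, which cell dissociation also induces, were lower in conditional cells. Their median was -0.73 over 20 genes (camera, adjusted p = 8.64e-11; adjusted p = 0.456 with an estimated correlation), 15 had all conditional values below both controls, Fos fell, and 8 were lower adjusted over the list alone. Hspa1a was at -1.78 (adjusted p = 0.0545). Epithelial genes had a median of -1.28 over 24 genes (camera, adjusted p = 6.40e-08; adjusted p = 0.456 with an estimated correlation), with Krt20 and Cdhr5 lower over all genes and 3 lower adjusted over the list alone. Stromal and endothelial genes had a median of -1.001 over 20 genes (camera, adjusted p = 0.000263; adjusted p = 0.740 with an estimated correlation), with 0 adjusted over the list alone and Col1a1 at -1.64 (-0.85 without control replicate 1). Against control replicate 2 alone these medians were -0.39 and -0.34, the stromal median was -1.82 against control replicate 1 alone, and the stromal list did not pass without control replicate 1 (adjusted p = 0.629). B cell genes had a median of -0.35 over 21 genes (camera, adjusted p = 0.00533; adjusted p = 0.733 with an estimated correlation), with 0 adjusted over the list alone and Ebf1 at -1.07. The B cell list did not pass without conditional replicate 3 (median -0.19, adjusted p = 0.0824), and its median was -0.60 without conditional replicate 2 and -0.61 with array weights. The replicate block repeats the -0.19 obtained without conditional replicate 3.

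Genes of macrophages, monocytes and dendritic cells were higher, with a median of 0.60 over 24 genes (camera, adjusted p = 1.67e-06; adjusted p = 0.456 with an estimated correlation). None passed over all genes, 4 were higher adjusted over the list alone, and Cd14 was at 2.41 and Itgax at 1.17. Granulocyte and mast cell genes had a median of 0.34 over 20 genes (camera, adjusted p = 4.13e-06; adjusted p = 0.350 with an estimated correlation), with 8 higher adjusted over the list alone, S100a8 at 1.32 and Kit at 2.17, and its median was 0.57 without control replicate 2 and 0.54 with the lower quartile filter. Natural killer and innate lymphoid genes had a median of 0.08 and a mean of 0.57 over 11 genes (camera, adjusted p = 0.00324; adjusted p = 0.698 with an estimated correlation). Tyrobp, a signalling adaptor of these receptors, rose 3.67-fold, and 4 were higher adjusted over the list alone. The natural killer list median turned to -0.04 without control replicate 1, where the list did not pass (adjusted p = 0.413), and to -0.01 after another quantile normalization, where it did. It was 1.004 under both filters on dim genes, 0.01 after median centring and 0.12 with array weights. Without conditional replicate 2, conditional replicate 3 and control replicate 2 it was 0.12, 0.28 and 0.56, so its size is not firm. The replicate block repeats the 0.28 obtained without conditional replicate 3. By camera, CD8 T cell genes (median 0.44, adjusted p = 0.0550) and gamma-delta T cell genes (median 0.28, adjusted p = 0.534, 4 of 8 listed genes measured) did not pass. Neither did erythroid genes (median 0.09, adjusted p = 0.542), ribosomal protein genes (median -0.02, adjusted p = 0.505) or sex-linked genes (median 0.08, adjusted p = 0.605). The sex-linked list mixes Xist (0.89) with Y-linked genes of either sign (Uty 0.44, Kdm5d -0.32), so its test says little about sex. Trgv1 and Trdv2-2, gamma and delta receptor variable segments past the threshold, named after their values were seen, were higher by 2.63 and 2.20. In control cells they lay at the 18.9 and 16.1 percentiles of all genes. Klrd1, the partner chain of Klrc1, was at 3.24 (adjusted p = 0.0501). Adjusted over the list alone, 2 CD8 genes and 1 gamma-delta gene were higher, and 0 erythroid, ribosomal or sex-linked genes passed. The CD8 list passed without conditional replicate 1, conditional replicate 3 or control replicate 2 (adjusted p = 0.0255, 0.0117 and 0.00107) and after quantile normalization, median centring or the replicate block (adjusted p = 0.0286, 0.0230 and 0.000295), but its median was 0.002 without control replicate 1 (adjusted p = 0.686) and 0.11 with the median filter (adjusted p = 0.819). The gamma-delta median turned to -0.11 with that filter, and the ribosomal list passed as lower without control replicate 1 (adjusted p = 0.00481).

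**Figure D2:**
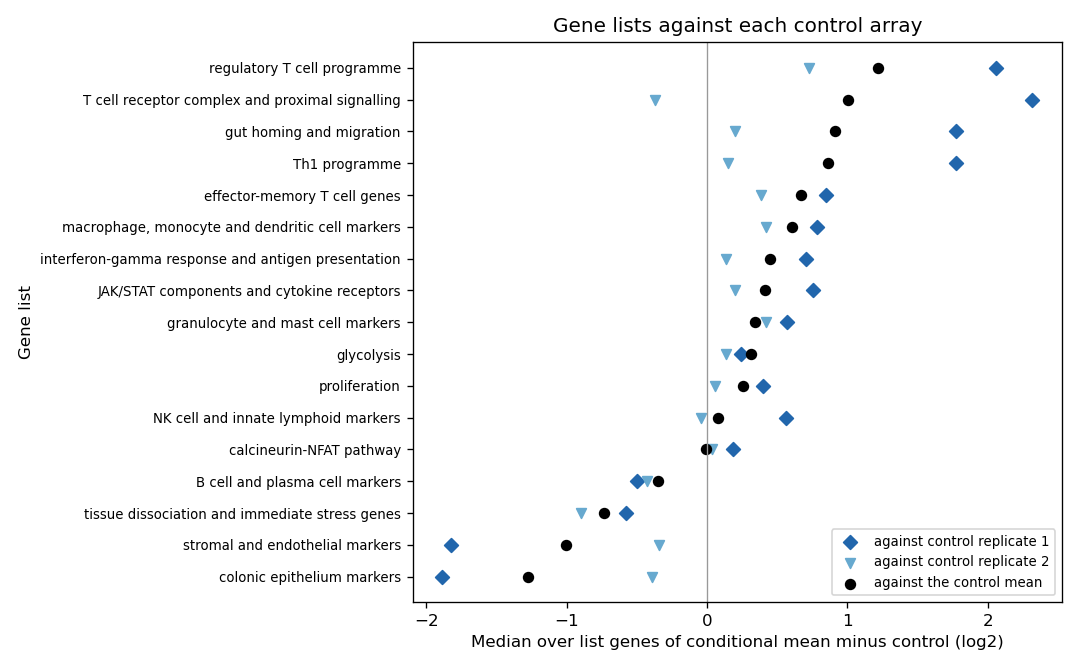
Median over the genes of each list of the conditional mean minus control, on the log2 scale, against control replicate 1, control replicate 2 and the mean of both, for the 16 lists that passed camera at a preset correlation and the calcineurin-NFAT list. The T cell receptor list lay at 2.32 against control replicate 1 and at -0.37 against control replicate 2.

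Control replicate 1 stood apart from the other arrays. The first principal component held 70.7% of the variance, with control replicate 1 at 83.3 and the other 4 arrays between -40.6 and -10.1. The second held 20.9% and set control replicate 2 apart, at -46.1 against 5.69 to 17.84 on the other 4 arrays. On control replicate 1 the mean level of T cell receptor genes was 8.50, against 10.71 to 11.15 on the other arrays. The mean level of epithelial genes there was 8.91, against 6.89 to 7.79. Stromal genes averaged 10.60 on control replicate 1 and 8.35 to 9.38 elsewhere.

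**Figure D3:**
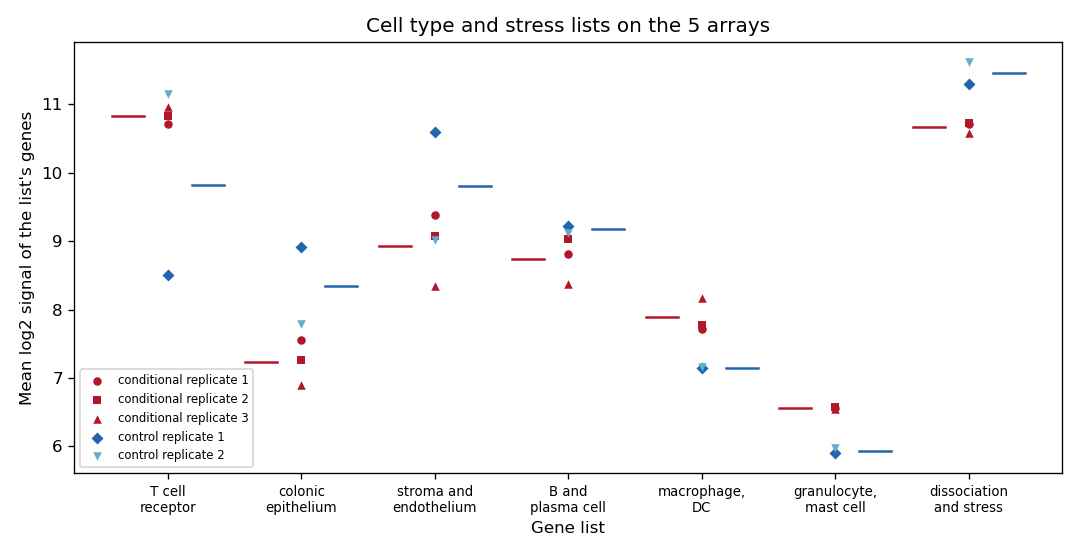
Mean log2 signal of the genes of 7 lists on each array, with short bars for the group means. Control replicate 1 had the lowest T cell receptor level (8.50) and the highest epithelial level (8.91), and both controls lay below all conditional arrays for macrophage and granulocyte genes.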

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

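Outside the genes analysed, 192 of the 11799 probe sets without a listed gene passed an adjusted p of 0.05 within that set, 192 higher in conditional arrays and 0 lower. They were flagged because this signal lies in data that no comparison above used. What these probe sets measure was not tested.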

How the results depend on the processing

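The alternatives were planned, except the T cell covariate, which was chosen after seeing the data. The 83 genes kept their direction under every alternative fit in which they were tested. Leaving out an array could not change it, since their groups were fully apart. The count of genes past the threshold stayed within 1.5 times under another quantile normalization (88), median centring (76), filters at the median (63) and lower quartile (81), averaged probe sets (72) and a variance trend with or without a robust prior (100). It was 275 (250 higher, 25 lower) over all probe sets, 13 (13 and 0) with array weights, 1086 (713 and 373) at an unadjusted p of 0.01, and 1648 (874 and 774) with the T cell covariate, a fit that met both control arrays almost exactly (leverage 0.996) and so rests on single arrays. Lower genes numbered 15 after quantile normalization, 14 after median centring and 4 with the median filter. Leaving out 1 array gave 0 to 5474 genes (0 to 2190 higher, 0 to 3284 lower). The lowest limma adjusted p without conditional replicate 1, 2 or 3 was 0.0557, 0.267 and 0.0621. Fewer arrays leave fewer degrees of freedom. The fits without a control array had equally few arrays and still called genes, so the number of arrays alone does not account for this. The fits without a control assume that the lone control varies like the conditional arrays. The 83 genes had been chosen by their p with both controls, so their passing again without 1 control adds no support.

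Gene lists past the threshold numbered 0 with an estimated correlation and 2 by fry. The Th1 median of 0.86 did not pass with an estimated correlation (adjusted p = 0.733) or by fry (adjusted p = 0.141), and leaving out an array moved it between 0.15 (without control replicate 1) and 1.78. Over its 17 alternatives the adjusted p ran from 2.10e-14 with the replicate block to 0.733 with an estimated correlation. The variance trend settings, with or without a robust prior, do not enter camera and so repeat the main list values. The naive T cell list reversed to 1.02 without control replicate 2, within a range from -0.45 to 1.02 when 1 array was left out. The T cell receptor list reversed to -0.0835 with the T cell covariate, which is that list's own mean, and to -0.37 without control replicate 1, within a range from -0.37 to 2.32. The Ppp3r1 difference, never past the threshold, was 0.0928 with the T cell covariate and lay between -0.25 and 0.15 with 1 array left out. The cause of these changes was not tested beyond this. Among single named genes, 1745 comparisons with an alternative kept their side of the threshold, 224 moved past it, 143 fell short of it and 16 changed sign without a call.

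With the replicate number as a block, 69 genes passed, 38 of them among the 83. Conditional replicate 3 is alone in its block and adds nothing to the group difference. The differences therefore equal those without conditional replicate 3 (Th1 median 0.868 in both), and the block is no separate alternative for them. Its p-values rest on fewer residual degrees of freedom than the main fit. No label says whether arrays of one number share an experiment. Deviations from the group means correlated at 0.40 for replicates 1 and -0.29 for replicates 2, and conditional replicate 3 has no partner. The highest value, 0.585, was between conditional replicate 3 and control replicate 2. With 2 controls, their deviations are exact opposites, so these correlations cannot decide whether arrays of one number are paired. Signal over background was not given per probe set, so dim genes were limited by the filters above alone.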

Other observations

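All tests in this part were chosen after the result was seen, except the splits of the arrays. Several further genes past the threshold, named here after their values were seen, are best known from innate cells. They were picked by hand. Of the 24 macrophage, monocyte and dendritic cell genes and the 20 granulocyte and mast cell genes in the fixed lists, 0 passed over all genes, although both lists passed camera at the preset correlation. Nlrp3, an inflammasome sensor, was higher by 2.68, Lcn2, an iron-sequestering protein of neutrophils and epithelium, by 3.06, Cxcl2, a neutrophil chemokine, by 2.34, Clec4d by 2.86, Cd33 by 1.96 and Mpeg1 by 2.31. In control cells Clec4d, Nlrp3 and Mpeg1 lay at the 13.5, 16.9 and 23 percentiles of all genes, with no call against background. The drug efflux pump genes Abcb1a and Abcb1b were higher by 1.91 and 2.74, the costimulatory ligand gene Cd80 by 2.53, and the killer receptor gene Klrb1b by 1.54.

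Control replicate 1 stood apart from the other arrays. A candidate explanation is that epithelial and stromal cells entered this sample. The 44 epithelial and stromal markers lay a median of 1.60 above the mean of the other 4 arrays, and the T cell receptor list 2.40 below. Of the 44, 30 lay above the median gene in control replicate 2, and 0 stand in another list. Epcam was at 10.57 against 7.27 to 8.23, and Col1a1 at 11.56 against 8.76 to 9.96. Car4 and Slc26a3 were higher in both controls than on every conditional array, but highest in control replicate 2. Car4 was at 7.93 in control replicate 1, 10.03 in control replicate 2 and 6.35 to 6.76 on conditional arrays. Slc26a3 was at 6.81, 8.16 and 4.99 to 5.14. Of the 24 epithelial markers, 13 had all conditional values below both controls and 1 above both. Comparisons against control replicate 2 alone are therefore not free of epithelial signal. Against control replicate 2 alone, 17 of 24 epithelial and 19 of 20 stromal markers were higher in control replicate 1. Whether a lower T cell share raised every other cell type alike cannot be decided here. The epithelial list lay 2.17 above the macrophage list in the offsets from the other 4 arrays (permutation test with 100000 resamples, two-sided, p = 0.00013). Most of those arrays are conditional, where macrophage genes were higher, and the test treats genes of 1 array as independent. Against control replicate 2 alone, the epithelial and macrophage medians of control replicate 1 were 1.085 and -0.28, which rests on single arrays. The sort on CD45, CD3 and CD4 is meant to remove epithelial and stromal cells. Stromal genes still averaged 8.35 to 10.60 on the 5 arrays, where the median gene lay at 7.335 to 7.529. How fully the sort removed such cells is therefore not known. Whether the sorted cells of control replicate 1 differed in biology was not tested.

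The T cell lists may be higher in conditional arrays because control replicate 1 held fewer T cells. For the T cell receptor list, the median against control replicate 2 alone was -0.37. The lower T cell share was read from that same list, so the list could not decide this explanation. For the regulatory T cell and Th1 lists it cannot be told apart from a group effect: without control replicate 1 the regulatory list passed (median 0.73, camera, adjusted p = 6.65e-06; adjusted p = 0.733 with all arrays and an estimated correlation) and the Th1 list did not (median 0.15, adjusted p = 0.176), and control replicate 2 alone decides both. Their means differed by 0.54 and 0.59 with the T cell receptor list mean as a covariate (limma on list means, adjusted p = 0.0349 and 0.0125), but that fit met both control arrays almost exactly (leverage 0.996) and so again rests on control replicate 2. An earlier test, replaced by this fit after its result was seen, left both open, since the list mean minus the T cell receptor list mean lay above the conditional means (-0.37 and -0.87) in control replicate 1 (0.38 and -0.37) and below them in control replicate 2 (-1.08 and -1.61), and an effect of losing calcineurin B, which the design names, stays untested.

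Myeloid genes were higher in conditional arrays, and macrophages, monocytes, dendritic cells or granulocytes in those samples are a candidate explanation that the tables leave open. Of 44 markers, 26 had all conditional arrays above both controls (a median of 6 and a central 95% range of 2 to 10 in 10000 random lists matched on mean level), which restates the pattern and would hold equally if the T cells expressed these genes. Of 8 abundant transcripts 5 did so, among them Lyz2 at 2.08, Cd14 at 2.41 and S100a9 at 1.35, while Ctss at 0.53, C1qa at 0.30 and Cst3 at 0.16 overlapped the controls. Of the 44, 0 stand in another list and 8 lay above the median gene in control replicate 2. The sort on CD3 and CD4 is meant to remove such cells, but how fully it did so was not tested. The source of the signal, myeloid cells or T cells of the conditional genotype, cannot be told apart here.

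The 5 arrays can be split into 3 and 2 in 10 ways, too few for a share under 0.05. The real split gave 83 genes, the highest of the others gave 0, and 1 of the 10 splits gave as many as the real one.

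Raised genes lay beside each other more often than random genes, which may mean that neighbouring genes change together. Of 74 genes, 12 had another raised gene among the 3 nearest tested genes on either side in the gene order of assembly GRCm38.p6, against a median of 2 and an upper limit of the central 95% of 6 in 10000 random sets matched on mean level. They included Klrc1 with Klrc2, Clec4d with Clec4e, Abcb1a with Abcb1b, Ttc39c with Cabyr, and Fes with Furin. Leaving out pairs whose symbols share their first 4 characters left 6, equal to that limit, so paralogs, whose probes could share signal, cannot be told apart from a wider effect.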
